A study of Mus musculus with 282 samples.

How the data were processed

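The data are single-cell RNA-seq profiles of 282 cells sorted as basal prostate stem cells from the prostates of male POET3 mice. These transgenic mice express ovalbumin in the prostate and are used as a model of prostatitis. The labels give each cell a condition, naive or inflamed, and a batch, 2 or 3. Per the labels' protocols, the tissue was digested with collagenase and trypsin, the cells were stained for viability, CD45, CD31, Sca-1 and CD49f and sorted, and the gates are not given in the sources used here. Cells were captured on a Fluidigm C1 instrument, amplified with SMARTer chemistry, made into libraries with a Nextera kit and sequenced as single-end reads. The chemistry adds no molecular identifiers, so a count is a read and not a molecule, and intervals and floors given here cover counting error only. Nothing in the labels marks the reads' strand, so reads of overlapping genes on opposite strands could not be told apart.

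The deposited values are raw counts of reads per gene and cell, in 1 table per batch with 48440 gene rows each. TopHat2, HTSeq, R 3.4.1, Seurat 1.4 and the genome build GRCm38.p6 are named, without roles or order, per the submitters' processing notes. How reads in more than 1 place in the genome were counted is not given in the sources used here. Genes with near-identical copies, such as the class I genes H2-K1 and H2-D1, the Gbp and Irg families, Krt6a and the Sprr and Ly6 genes, are therefore uncertain in part. The tables had 0 rows that named no gene and 0 spike-in rows. Gene symbols and coordinates came from the GENCODE annotation of GRCm38, in which 48058 of the 48440 gene identifiers matched a symbol.

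Cells with under 1000 detected genes or under 50000 counts were left out, which removed 14 cells and kept 53 naive cells of batch 2, 59 naive cells of batch 3, 80 inflamed cells of batch 2 and 76 inflamed cells of batch 3. No cell had counts identical to those of another cell. No doublet caller was run. Total counts ranged from 2725 to 2219764 per deposited cell. Kept cells were clustered with scanpy 1.11.5 on log-normalised counts (2000 variable genes, 20 components centred per batch, 15 neighbours, Leiden resolution 0.8), and clusters were named from fixed markers. The 4 clusters were led by Atg2a, Sik3 and Slc43a2, by Nrep, Fignl1 and Tecpr2, by the mitotic genes Hmmr, Kif23 and Cenpf, and by Snupn, Tlr2 and Tnfrsf23. Socs3 and Tlr2, which are linked to immune signalling, were among the 10 leading genes of the first and the last. In each cluster 9 or 10 of the 10 basal markers and 5 or 6 of the 14 luminal markers were detected, and all 4 were named basal epithelial-like.

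Cells are not replicates. Each GEO sample is 1 cell and the labels name no animal, so counts were summed over the kept cells of each condition and batch, and the 4 sums were the tested units. With the batch in the model, p-values rest on how far the difference between the conditions varies between the 2 batches, which may be technical. The test moderates this spread across genes (2.66 prior beside 1 residual degree of freedom). If a batch is not an independent set of animals, each condition is in effect 1 sample. The main test was edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr on condition) with R 4.3.3, with condition and batch in the model, 1 residual degree of freedom, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are inflamed over naive on the log2 scale with standard errors from the fit. Within-batch folds of single genes came from log CPM with a prior count of 2, and CPM values are counts scaled by the TMM-corrected library size. The labels name the batch, and this is what pairs the sums. Across 14713 genes the batch deviations of the naive and inflamed sums had a correlation of -0.01.

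Gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and, beside it, with an estimated correlation. The preset value is a choice and was not measured here. The estimated form rests on 1 residual degree of freedom. Even the interferon gamma list, with camera p = 4.16e-19 at the preset correlation, had camera p = 0.063 with an estimated one. That form could hardly call any list, so its lack of calls does not tell whether correlation explains the preset calls. Of 40 lists, 35 had at least 3 measured members and were tested. A list's median within a batch was also ranked among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Where a sum was 0, the list medians given here set it to 3 counts. Shares of cells with a read have exact Clopper-Pearson intervals at 95%, except that a share of 0 is given in the text with a limit of 3 cells of the total, which lies below the upper Clopper-Pearson bound drawn in the figure. Shares are given also for cells thinned to 500000 counts, which 25 shallower cells could not supply (7 naive and 10 inflamed cells of batch 2, and 4 of each in batch 3).

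The genes named in the text were set by a rule: the 10 genes per direction with the smallest p that had the same sign in both batches and a read in at least 20% of the cells of the higher condition in both, up to 4 genes with the smallest p per list, and a fixed set of sort markers, keratins, interleukin 1 genes and others. Some of these genes, and 2 of the tested lists, 1 of them called lower, are not reported here. The rule, the lists, the tests and most alternatives were chosen before the data were examined. Alternatives were DESeq2 1.42.0, other normalization factors, other filters on genes and cells, no block, each sum left out in turn, thinned cells, limma on mean CPM per cell, each gene's highest cell left out, and no cells whose title numbering starts again. A filter to genes with a read in at least 20% of the cells of either condition in both batches, alone and with other choices, was added after the main test gave no gene, and a sterol synthesis list was added after its first members had been seen.

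The test was tested on simulated counts drawn from the real means and library sizes and from edgeR's own gene-wise dispersions. For each gene a batch shift shared by both conditions was added, whereas the real batch deviations had a correlation of -0.01. Over all genes, 100 genes were changed 8-fold and 100 changed 64-fold among 14087 genes tested. edgeR recovered 17 and 60 of them and called 10 unchanged genes. DESeq2 recovered 41 and 82 and called 452 unchanged genes. In the simulation restricted to 6717 genes found in 20% of cells, edgeR recovered 47 and 89 with 10 unchanged genes called, and DESeq2 66 and 95 with 116. The list that was moved was called in both simulations, and 4 and 0 of 200 random lists had p under 0.05. Genes were drawn independently and the moved list held changes of 8-fold and 64-fold, so it could hardly be missed. The simulation says nothing about lists of genes that vary together.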

Results

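Single-cell transcriptomes were compared between basal prostate stem cells of naive and inflamed mouse prostates. The 282 cells comprised 55 naive and 85 inflamed cells in batch 2, and 64 naive and 78 inflamed cells in batch 3. After filtering, 53 and 80 cells remained in batch 2 and 59 and 76 in batch 3, and 14 were left out. Their median depth was 971069 counts in naive batch 2, 840863 in naive batch 3, 1001872 in inflamed batch 2 and 998865 in inflamed batch 3, and the median number of detected genes was 4739, 3432, 4683 and 4109. The sums over cells held 52061533 and 50105953 counts for naive batches 2 and 3 and 79225330 and 78459122 for inflamed batches 2 and 3. Mitochondrially encoded genes took a median of 2.67% and 2.26% of the counts of naive cells and 3.73% and 2.82% of those of inflamed cells.

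The main comparison, inflamed against naive, asks how inflammation alters these cells, in particular through the interleukin 1 receptor antagonist, which the study's title names. In both batches, inflamed cells had more reads of most measured genes of the interferon gamma response, antigen presentation, interleukin 1 and squamous keratin lists, and fewer of most immediate early genes, such as Egr1 and Fos. No gene passed after adjustment. The lists were called with a preset correlation between genes and not with an estimated one, which could hardly call any list here. Irgm1, an interferon-induced GTPase, stood at 1.65 and 3.08 CPM in naive batches 2 and 3 against 303 and 637 CPM in the inflamed sums (log2 fold change 7.61 ± 0.43, SE, n = 2 sums per condition), where 1 cell gave 88.2% and 90.4% of the naive reads. Ptgs2, the inducible cyclooxygenase, was 16.8-fold and 16.9-fold higher, and Egr1 was 15.1-fold and 11.7-fold lower.

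No single gene passed the threshold. edgeR's quasi-likelihood test called 0 genes higher and 0 lower of 14713 (lowest adjusted p = 0.568), with 742 higher and 475 lower at an unadjusted p under 0.05. DESeq2 called 927 higher and 534 lower. In simulated data it called 452 unchanged genes against 10 by edgeR. Those data used edgeR's own dispersions and an added batch shift, so they cannot tell how many of the DESeq2 calls here are false. The direction within a batch was the same in both batches for 59.2% of the genes (Pearson's r 0.24 and Spearman's rho 0.22 across genes, which are not independent replicates). Of the 1424 genes found in at least 20% of cells and 2-fold or more higher in batch 2, 1028 (72.2%) were higher in batch 3, and of 1200 such genes lower in batch 2, 885 (73.8%) were lower in batch 3, where 48.6% of all genes found in 20% of cells were higher. Over all genes tested, the shares were 65% and 58.5%. All single-gene values below therefore describe genes that missed the threshold after adjustment. Many of the low naive sums rest largely on 1 cell, and this share is given for some genes only.

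Il1rn encodes the interleukin 1 receptor antagonist (ENSMUSG00000026981; GRCm38 chromosome 2, 24336853 to 24351494, plus strand). It had 0 counts in naive batch 2 and 6 counts (0.126 CPM) in naive batch 3, against 99.2 and 188.8 CPM in inflamed batches 2 and 3. In batch 2 this was at least 1870-fold higher, against a floor of 3 counts per library. That floor covers counting error and not which cells were sampled. Its unadjusted p was 0.00198, and its adjusted p was 0.568 by edgeR and 8.34e-27 by DESeq2. A read of Il1rn was found in 0 of 53 naive cells of batch 2 (3 cells of 53 would be 5.66%), and in 8.47% (95% interval 2.81 to 18.7) of naive cells of batch 3. The share was 41.2% (30.4 to 52.8) and 27.6% (18 to 39.1) of inflamed cells. In cells thinned to equal counts, the shares were 0, 5.45%, 34.3% and 20.8%. With at least 5 reads required, they were 0 and 0 in naive cells and 22.5% and 13.2% in inflamed cells.

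Other interleukin 1 genes differed in the same direction. Il1a, an agonist of the receptor (chromosome 2, 129299610 to 129309972), had 0 and 0.0843 CPM in the naive sums and 147.5 and 78.4 CPM in the inflamed sums. Il1r1, the signalling receptor, had 0.301 and 6.83 CPM against 97.2 and 132.7 CPM, and Il1r2, the decoy receptor, had 50.3 and 18.8 CPM against 87.3 and 181.5 CPM. In naive batch 3, 1 cell gave 98.1% of the Il1r1 reads and 89.9% of the Il1r2 reads. Il1b had 0 reads in all 4 sums. Of the 15 measured genes of the interleukin 1 list, 10 were higher in both batches and 1 lower in both. There were 4 higher at an unadjusted p under 0.05, 2 higher adjusted over the list alone and 0 over all genes. The list median was 2.33 in batch 2 and 2.69 in batch 3 on the log2 scale, at the 99.99th percentile of random lists in each, and camera called the list higher (adjusted p = 0.000832). The list was not called with an estimated correlation (camera adjusted p = 0.716), a form that could hardly call any list here.

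Several other named genes went both ways. Tsc22d3, a glucocorticoid target, was 11.2-fold and 8.15-fold lower, at 324 and 384 CPM in naive against 28.9 and 47.1 CPM in inflamed sums. Hoxb13, a prostate homeobox factor, had 119.7 and 108.6 CPM in naive and 29.4 and 13 CPM in inflamed sums. Hpgd had 149.4 and 100.2 CPM against 21.7 and 37.3 CPM. Nedd4l had 0.638 and 6.47 CPM in naive against 77.6 and 78 CPM in inflamed sums, and Map7d1 8.12 and 29.8 CPM against 84.5 and 105.6 CPM. Fkbp5, also a glucocorticoid target, was 17.3-fold lower in batch 2 and 1.37-fold lower in batch 3.

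Interferon gamma response genes formed the list with the lowest adjusted p (camera adjusted p = 1.45e-17, and adjusted p = 0.716 with an estimated correlation). Of 28 measured genes, 23 were higher in both batches and 1 lower in both. There were 18 higher and 1 lower at an unadjusted p under 0.05, 17 higher adjusted over the list alone and 0 over all genes. The median was 6.85 in batch 2 and 8.26 in batch 3, above all random lists. Ido1, which degrades tryptophan, had 0 counts and 2 counts in the naive sums and 186.2 and 295 CPM in the inflamed sums, and Iigp1, another interferon-induced GTPase, had 0 and 0.695 CPM against 144.4 and 669 CPM. Gbp4 had 0 and 3 counts in the naive sums and 47.5 and 134.5 CPM in the inflamed sums. Ubd, a ubiquitin-like protein induced by cytokines, was 29-fold and 53.7-fold higher, and 1 cell gave 93.8% and 97.6% of its naive reads.

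Antigen presentation genes were higher with them. For MHC class II, 7 of 9 measured genes were higher in both batches, 5 at an unadjusted p under 0.05, 4 adjusted over the list alone and 0 over all genes (medians 6.72 and 8.85, camera adjusted p = 1.52e-08, and adjusted p = 0.716 with an estimated correlation). H2-Aa, a class II chain, had 0 counts and 5 counts in the naive sums and 160 and 1279 CPM in the inflamed sums. In batch 2 it was at least 3010-fold higher against a floor of 3 counts, which covers counting error only. Reads of H2-Aa were found in 0 and 5.08% of naive cells and in 63.8% and 97.4% of inflamed cells. H2-Ab1, its partner chain, had 0 and 0.190 CPM in naive and 183.2 and 884 CPM in inflamed sums. Cd74, the invariant chain, had 5.16 and 7.18 CPM in naive and 543 and 3305 CPM in inflamed sums, and 1 cell gave 99.7% and 94.1% of its naive reads. For MHC class I, 19 of 21 genes were higher in both batches, 11 at an unadjusted p under 0.05, 6 adjusted over the list alone and 0 over all genes (medians 2.53 and 2.78, camera adjusted p = 1.54e-10, and adjusted p = 0.716 with an estimated correlation). B2m was 6.70-fold and 4.99-fold, H2-K1 5.79-fold and 7.84-fold and H2-D1 13.3-fold and 7.33-fold higher, and the latter pair share near-identical sequence. Ptprc, which encodes the leukocyte marker CD45, had 0 reads in all 4 sums. So did other leukocyte genes such as Laptm5, Srgn, Tyrobp and Lyz2, and as these zeros are unexplained they do not tell whether leukocytes were present.

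**Figure D1:**
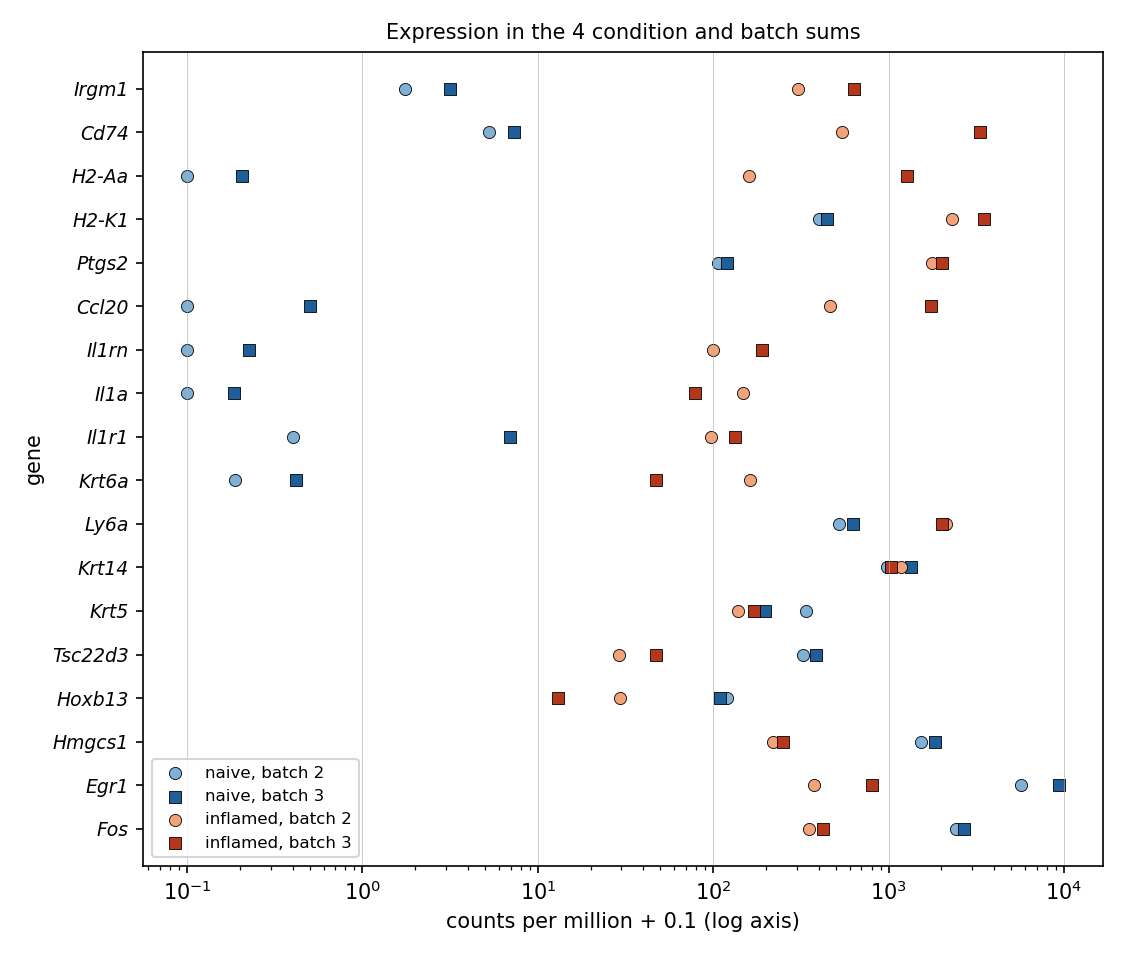
CPM plus 0.1 on a log axis for 18 genes, with 1 point per sum of cells (blue, naive; orange and red, inflamed; circles, batch 2; squares, batch 3). H2-Aa, Il1rn and Il1a lie at 0 in naive batch 2, Krt14 differs little between the sums, and Egr1 and Fos lie higher in both naive sums.

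Genes that respond to NF-kB included Ptgs2 at 106.2 and 120 CPM in naive and 1780 and 2027 CPM in inflamed sums, and the chemokine Ccl20 at 0 and 0.40 CPM against 466 and 1753 CPM, of which 38.9% and 53.1% came from 1 cell each. Cxcl2 was 10.5-fold and 53.7-fold and Lif 7.12-fold and 4.14-fold higher. In this list 19 of 28 genes were higher in both batches and 1 lower in both, 8 higher at an unadjusted p under 0.05, 2 adjusted over the list alone and 0 over all genes (medians 1.98 and 1.19, camera adjusted p = 5.91e-08, and adjusted p = 0.716 with an estimated correlation). The type I interferon list had 16 of 24 genes higher and 3 lower in both batches, 7 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (medians 1.55 and 2.94, camera adjusted p = 0.000146, and adjusted p = 0.841 with an estimated correlation, and 0.147 with the 20% gene filter). Its member Oasl2 was 4.99-fold and 5.83-fold higher, and 1 cell gave 86.2% and 98.2% of its naive reads. Acute phase and antimicrobial genes were higher in both batches for 8 of 9, and 4 were higher at an unadjusted p under 0.05 and 1 adjusted over the list alone (medians 6.38 and 1.21, camera adjusted p = 0.000832, and adjusted p = 0.716 with an estimated correlation, and 0.309 with the 20% gene filter). Slpi, a protease inhibitor, had 0.390 CPM and 3 counts in naive against 80.7 and 94.3 CPM, the lectin Reg3g 0 and 5 counts against 9618 and 2177 counts, and Lcn2 was 3.52-fold and 1.55-fold higher. For JAK-STAT3 signalling, 9 of 18 genes were higher and 3 lower in both batches, with 2 higher adjusted over the list alone, and the list was not called (medians 0.76 and 0.42, adjusted p = 0.0845, and adjusted p = 0.841 with an estimated correlation), although it was with the 20% gene filter (0.0133) and with DESeq2 (0.0238). Jak2 was 26.8-fold and 22.6-fold, Osmr 7.24-fold and 5.95-fold and Il13ra1 9.52-fold and 4.0-fold higher.

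Keratins of squamous and stressed epithelium were higher, whereas Krt14, Krt8 and Krt18 differed little. Krt6a, a keratin of wounded epithelium, had 0.0886 and 0.316 CPM in naive and 162.2 and 47.2 CPM in inflamed sums. Krt13 had 14.7 and 2.13 CPM in naive and 259 and 343 CPM in inflamed sums. Krt23 was 15.3-fold and 19.1-fold and the cornified envelope gene Sprr1a 3.97-fold and 3.34-fold higher. Of 18 genes of this list, 14 were higher and 2 lower in both batches, 6 higher at an unadjusted p under 0.05, 5 adjusted over the list alone and 0 over all genes (medians 4.03 and 2.45, camera adjusted p = 2.06e-07, and adjusted p = 0.716 with an estimated correlation). The proximal luminal list, genes of the ducts near the urethra, had 10 of 13 genes higher and 0 lower in both batches, 8 at an unadjusted p under 0.05 and 5 adjusted over the list alone (medians 3.38 and 1.69, camera adjusted p = 9.38e-08, and adjusted p = 0.841 with an estimated correlation). Krt4 was 9.03-fold and 6.75-fold and Ly6d 5.16-fold and 5.30-fold higher, and Wfdc2 had 0.301 and 2.15 CPM in naive against 120.6 and 63.5 CPM in inflamed sums. Ly6a, which encodes the sort marker Sca-1, was 4.06-fold and 3.23-fold higher (523 and 630 CPM against 2121 and 2031 CPM), and Itga6, which encodes CD49f, 1.47-fold and 1.29-fold higher. The cells were sorted on both proteins, and the gates, which can set these levels, are not given in the sources used here.

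Krt5, Krt14 and Krt17 had reads in at least 91.5% of the cells of every sum, and Trp63 in 66.2% to 100%. Krt5 had 339 and 199 CPM in naive and 139.3 and 170 CPM in inflamed sums, and Krt14 976 and 1347 CPM against 1180 and 1027 CPM. The log2 fold changes of Krt14, Krt8 and Krt18 were -0.06 ± 0.30, -0.03 ± 0.43 and -0.18 ± 0.31 (SE, n = 2 sums per condition), with opposite signs in the batches, and that of Krt8 turned positive under upper-quartile scaling. Trp63 was 3.24-fold lower in batch 2 and 1.17-fold lower in batch 3, Krt17 was 4.11-fold and 1.57-fold higher, and Sult5a1 was 2.39-fold and 1.85-fold lower. The basal list (18 genes, medians 0.26 and 0.03, adjusted p = 0.693, and adjusted p = 0.898 with an estimated correlation) and the 10 basal markers (medians 0.25 and 0.05, adjusted p = 0.514, and adjusted p = 0.841 with an estimated correlation) were not called, with 0 genes adjusted over the list alone in each. The luminal list (20 genes, medians 0.21 and -0.45, adjusted p = 0.655) and the 14 luminal markers (medians -0.19 and -1.04, adjusted p = 0.67) were not called either (adjusted p = 0.906 with an estimated correlation for both), with 0 and 2 genes higher adjusted over the list alone. Within them Krt19 was 19.2-fold and 6.14-fold higher and Defb50 had 398 and 185.7 CPM against 77.6 and 56.3 CPM. Hemidesmosome and basement membrane genes were higher in both batches for 13 of 22 and lower for 3 (medians 0.45 and 0.30, adjusted p = 0.0845, and adjusted p = 0.841 with an estimated correlation, and 0.0436 with DESeq2, with 0 adjusted over the list alone), among them Itgb6 at 4.86-fold and 2.29-fold, and Tnc, a matrix protein of wounds, with 0 and 4 counts in naive and 110 and 43.9 CPM in inflamed sums. Stem and progenitor genes went both ways, 9 of 22 higher and 8 lower in both batches (medians -0.55 and 1.08, 2 higher adjusted over the list alone, adjusted p = 0.318, and adjusted p = 0.887 with an estimated correlation). Cd44 was 4.67-fold and 7.5-fold higher, and Aldh1a1 was 2.74-fold and 2.89-fold lower.

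Immediate early and dissociation stress genes were the lower list with the smallest adjusted p. Of 30 measured genes, 25 were lower and 1 higher in both batches, 16 lower at an unadjusted p under 0.05, 15 adjusted over the list alone and 0 over all genes (median -1.58 in each batch, below all random lists, camera adjusted p = 3.19e-15, and adjusted p = 0.716 with an estimated correlation). Egr1 (chromosome 18, 34859823 to 34864984) had 5671 and 9366 CPM in naive and 376 and 802 CPM in inflamed sums, with a log2 fold change of -3.73 ± 0.27 (SE, n = 2 sums per condition). Fos was 6.94-fold and 6.30-fold, Nr4a1 14.5-fold and 9.10-fold and the heat shock gene Dnajb1 5.81-fold and 5.20-fold lower. Jun was 7.17-fold and 5.52-fold lower and Nr4a2 had 447 and 227 CPM against 44.5 and 21.7 CPM.

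In the list of G2 and M phase, 23 of 28 genes were higher and 0 lower in both batches, 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone (medians 2.45 and 7.04, camera adjusted p = 3.71e-09, and adjusted p = 0.841 with an estimated correlation, and 0.345 with the 20% gene filter). Cenpf had 1.33 CPM and 2 counts in naive against 46.5 and 30.2 CPM in inflamed sums, and Tacc3 1.42 and 1.12 CPM against 49.3 and 22 CPM. In the naive sums, 1 cell gave 95% and 96.2% of the Tacc3 reads. These reads came from few cells: reads of at least 10 of the 28 genes were found in 2 of 53 and 0 of 59 naive cells and in 6 of 80 and 9 of 76 inflamed cells, or 3.77% (0.46 to 13), 0 (3 cells of 59 would be 5.08%), 7.5% (2.8 to 15.6) and 11.8% (5.56 to 21.3). In thinned cells these were 2 of 46, 0 of 55, 6 of 70 and 8 of 72. The S phase list of 25 genes was called lower (camera adjusted p = 0.0328, and adjusted p = 0.841 with an estimated correlation), with 4 genes lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Its median was -1.27 in batch 2 and 0.09 in batch 3, and the call was lost without the naive batch 2 sum (0.681), without the inflamed batch 2 sum (0.247), without the cells whose numbering starts again (0.057) and with the 20% gene filter (0.0744). Clspn had 52.4 and 6.17 CPM in naive and 0.178 and 0.0526 CPM in inflamed sums, and Mcm5 was 6.48-fold and 3.73-fold lower. In naive batch 3, 1 cell gave 99.7% of the Clspn reads, and 1 cell gave 76.1% of the Mcm5 reads.

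**Figure D2:**
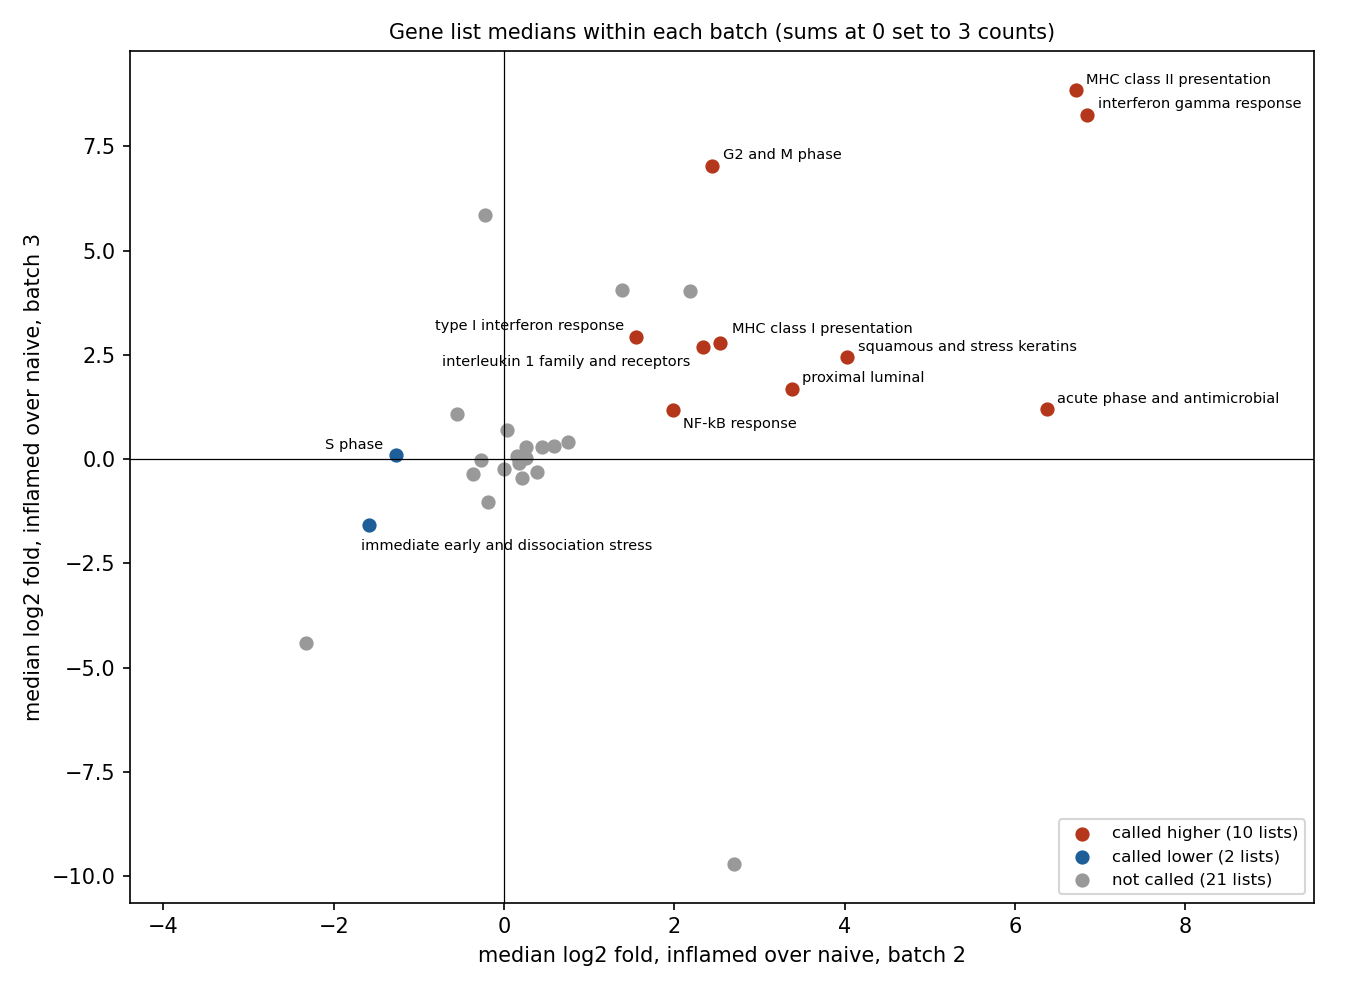
Median log2 fold of inflamed over naive for each of 33 gene lists, batch 2 on the horizontal and batch 3 on the vertical axis, with sums at 0 set to 3 counts; colour shows the camera call with a preset correlation. The 10 lists called higher lie above 0 in both batches, the immediate early list lies at -1.58 in both, and S phase lies below 0 in batch 2 alone; with an estimated correlation 0 lists were called.

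Beyond these lists, the genes with the smallest p that were higher included Anxa1, a phospholipid-binding regulator of inflammation, at 398 and 334 CPM in naive and 4560 and 2598 CPM in inflamed sums. Gpx2, a glutathione peroxidase, was 49.3-fold and 47.4-fold higher, and Nipal1 had 0.975 and 0.40 CPM against 350 and 74.9 CPM. In naive batches 2 and 3, 1 cell gave 47.8% and 98.3% of the Gpx2 reads. For Nipal1 these shares were 100% and 10.5%. Those lower included Hmgcs1, an enzyme of sterol synthesis, at 1529 and 1843 CPM against 219 and 249 CPM, Insig1, a regulator of that pathway, which was 25.1-fold and 16.6-fold lower, and Scpep1, a carboxypeptidase, which was 10.1-fold and 14.7-fold lower. CT010467.1, annotated as ribosomal RNA, was 4.75-fold and 6.23-fold lower, at 7361 and 4739 CPM in naive and 1551 and 761 CPM in inflamed sums.

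Metabolic and stress lists were not called. Glycolysis and hypoxia genes had medians of 0.26 and 0.30 (23 genes, adjusted p = 0.641, and adjusted p = 0.902 with an estimated correlation), with Hk2 5.51-fold and 3.97-fold higher and 1 gene adjusted over the list alone. Oxidative phosphorylation (33 genes, medians -0.27 and -0.01, adjusted p = 0.235, and adjusted p = 0.853 with an estimated correlation) and ribosomal protein genes (84 genes, medians 0.01 and -0.23, adjusted p = 0.277, and adjusted p = 0.906 with an estimated correlation) had 0 genes adjusted over the list alone. So did mitochondrially encoded genes (24 genes, medians 0.15 and 0.07, adjusted p = 0.761, and adjusted p = 0.903 with an estimated correlation), in which mt-Co1 had 3952 and 3827 CPM in naive and 14280 and 9429 CPM in inflamed sums. Oxidative stress genes (22 genes, medians 0.39 and -0.31, adjusted p = 0.803, and adjusted p = 0.943 with an estimated correlation) had 1 gene higher adjusted over the list alone, Gpx2, and lower values of Sod1, 4.41-fold and 2.41-fold. The apoptosis and p53 list (23 genes, medians 0.59 and 0.32, adjusted p = 0.235, and adjusted p = 0.841 with an estimated correlation) held Pmaip1, a pro-apoptotic gene, at 0.0354 and 0.147 CPM against 174.7 and 69 CPM, with 0 genes adjusted over the list alone, and the unfolded protein list (20 genes, medians 0.17 and -0.09, adjusted p = 0.926, and adjusted p = 0.943 with an estimated correlation) held Atf4 at 1017 and 1047 CPM against 535 and 509 CPM, also with 0. Notch and Wnt genes had medians of -0.36 and -0.35 (18 genes, adjusted p = 0.318, and adjusted p = 0.841 with an estimated correlation, with 0 adjusted over the list alone), with Hes1 at 292 and 241 CPM against 93.4 and 127.3 CPM. Genes of the epithelial to mesenchymal transition (13 genes, medians 0.04 and 0.69, adjusted p = 0.785, and adjusted p = 0.906 with an estimated correlation) had 1 higher and 1 lower adjusted over the list alone, Inhba with 3 counts and 1 count in naive against 54.8 and 34.9 CPM, and Sparc at 7.59-fold and 5.29-fold lower.

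Many of the markers of other cell types had too few reads to be tested. B cell, T and NK cell, erythroid, pan-leukocyte and neuroendocrine or glial lists had under 3 measured members and were not tested. Myeloid markers (3 measured of 13, medians 2.18 and 4.02, adjusted p = 0.125, and adjusted p = 0.841 with an estimated correlation) included Cd14, at 22.3 and 0.379 CPM in naive and 133.4 and 156.9 CPM in inflamed sums. Both medians are the value of Ly6c2, which had 3 and 1 reads in naive and 19 and 26 in inflamed sums. The remaining member, Cd68, was not higher in batch 2 (20.4 against 20.1 CPM). Smooth muscle markers (7 of 10, medians 1.39 and 4.06, adjusted p = 0.124, and adjusted p = 0.841 with an estimated correlation, but called higher with DESeq2 at 0.0132) had 1 gene higher adjusted over the list alone, Rgs5, with 0 and 2 counts in naive against 18.5 and 103.2 CPM. Endothelial markers (3 of 11, medians -2.33 and -4.42, adjusted p = 0.358, and adjusted p = 0.841 with an estimated correlation), fibroblast markers (3 of 12, medians -0.22 and 5.86, adjusted p = 0.934, and adjusted p = 0.969 with an estimated correlation) and seminal vesicle markers (4 of 8, medians 2.70 and -9.71, adjusted p = 0.216, and adjusted p = 0.853 with an estimated correlation, but called lower with DESeq2 at 0.0129) rested on few genes. Dcn, a fibroblast marker, had reads in 100% of the cells of every sum, at 3933 and 4369 CPM in naive and 3377 and 4397 CPM in inflamed sums, and its log2 fold change was -0.11 ± 0.23 (SE, n = 2 sums per condition). Svs2, a secretory protein of the seminal vesicle, had reads in 1.9% and 49.2% of naive and in 18.8% and 0 of inflamed cells. Pecam1, which encodes CD31, had reads in 3.77%, 0, 1.25% and 2.63% of the cells.

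**Figure D3:**
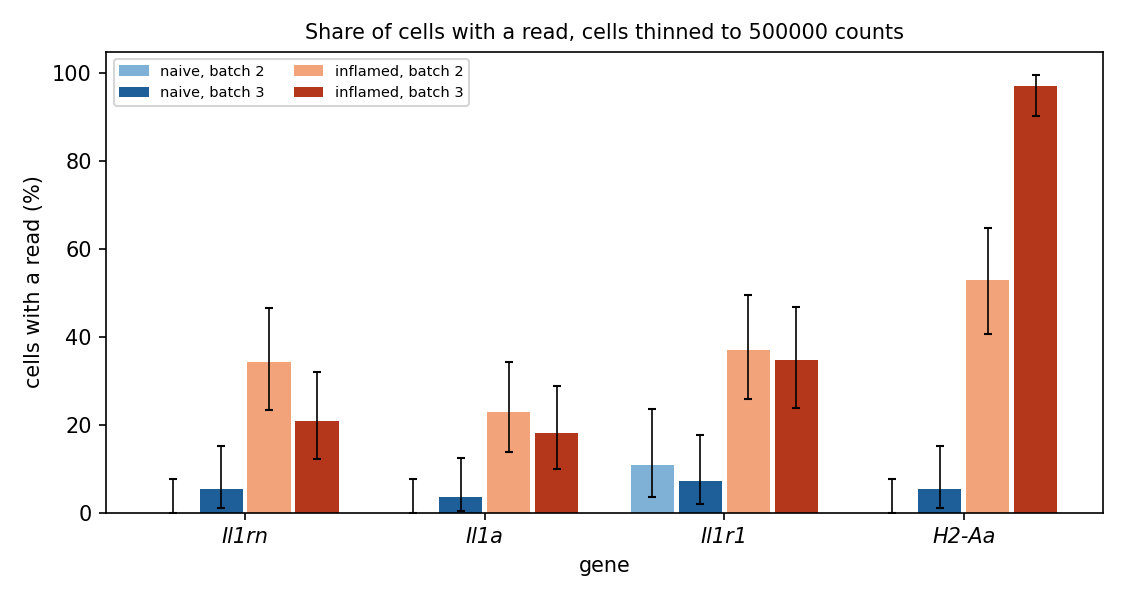
Percent of cells with a read of 4 genes, in cells thinned to 500000 counts (46, 55, 70 and 72 cells in naive batches 2 and 3 and inflamed batches 2 and 3); bars are 95% Clopper-Pearson intervals, which cover counting error only. Il1rn reaches 34.3% and 20.8% of inflamed cells, against 0 and 5.45% of naive cells.

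The comparison of basal epithelial-like cells used the same cells, since every cluster carried that name. Most naive cells lay in the cluster led by Nrep, Fignl1 and Tecpr2, and most inflamed cells in those led by Snupn, Tlr2 and Tnfrsf23 and by Atg2a, Sik3 and Slc43a2. The counts were the same: 0 genes higher and 0 lower by edgeR's quasi-likelihood test, with 742 and 475 at an unadjusted p under 0.05, and 927 and 534 by DESeq2. The batches themselves were compared in the same model as a technical reference. edgeR called 0 genes as different between batches, with 420 at an unadjusted p under 0.05, and DESeq2 called 393.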

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

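The tests of leukocytes, of the cells with restarted numbering, of single cells and of depth were chosen only after the result was seen, and the test of handling before it.

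The 14 cells left out for few genes or counts had a signal of the same kind as the kept cells. In the 7 inflamed ones, a median of 1.43% of the counts (0.442 to 4.78) fell on 56 genes of the interferon gamma, MHC class I and MHC class II lists, against 0.225% (0.12 to 1.01) in the 7 naive ones. Kept inflamed and naive cells had medians of 1.93% and 0.421%. The tests of the report leave these 14 cells out, and the alternative without a cell filter includes them.

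The first pattern weighed is the higher level of those 3 lists in inflamed cells. The test of leukocytes or their RNA as a source could not decide. Of the inflamed cells with 5 or more reads of H2-Aa or H2-Ab1, 14.4% (8.47 to 22.4) had a read of Lcp1 or Cd52. Vim was in 0 of these cells, but it had reads in only 2 naive and 2 inflamed kept cells, so its absence says little. Lcp1 and Cd52 are the 2 of 9 pan-leukocyte markers with any read, and the 0 reads of the other 7 are unexplained. Lcp1 was also found in 18 of 53 naive cells of batch 2, so a read of it need not mark a leukocyte. Reads of the myeloid marker Cd14 were found in 20.8% and 27.1% of naive and in 51.2% and 60.5% of inflamed cells. Those of Ly6c2 were found in 5.66% and 1.69% against 20% and 23.7%, with only 19 and 26 reads in the inflamed sums. Both went with the pattern, but Cd68 did not in batch 2 (18.9% and 5.1% of naive, 17.5% and 11.8% of inflamed cells). Cd14 had only 18 reads, in 16 cells, in naive batch 3, against 11928 in inflamed batch 3. It is also a member of the NF-kB list, which was called higher, so its reads need not mark myeloid cells. Lyz2, Adgre1, Csf1r, Tyrobp, Fcer1g, C1qb and S100a8 had 0 reads in kept cells. Krt17 had reads in 100% of the cells of both inflamed sums, so no cell with MHC class II reads lacked reads of this keratin. Among kept cells, this argues against leukocytes without keratin RNA as the source. Leukocyte RNA, doublets of a leukocyte and an epithelial cell, and leukocytes with stray keratin reads stay open. The restarted numbering of 13 inflamed cells was argued against by a batch 2 median of 4.16 without them and 4.13 with them (log2). Once each gene's highest cell was left out of every sum, the medians were 3.57 and 7.19, against 4.13 and 4.84 with it. Single cells thus moved the size but not the direction of these medians. The naive sums lost a cell too, which can raise a fold: for Cd74, 1 cell gave 99.7% and 94.1% of the naive reads. As only 1 cell per gene and sum was left out, the test does not decide on a few cells with most of the counts. What stays open beside the leukocyte sources named and a few cells with most of the counts is anything else that differed between the mice or preparations of the 2 conditions. A response of the epithelial cells to interferon gamma in the inflamed prostate may explain the pattern, as a hypothesis found and tested on the same data.

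The other pattern is the lower level of immediate early genes in inflamed cells. The medians stayed at -1.38 and -1.53 in thinned cells. Thinning mainly evens the weight of the cells and leaves a gene's expected share of a cell's counts unchanged. This test could therefore hardly have pointed to depth, and it does not decide on it. Handling, such as the time from digestion to lysis, cannot be told apart from the condition, because each condition was prepared from its own tissue: the list differed between batches by 0.46 in naive and 0.24 in inflamed cells, less than the -1.58 between conditions, but a handling step tied to the condition would repeat in both batches. The digestion itself can induce these genes, so the difference may lie in the response to dissociation and not in the tissue; a biological difference of the inflamed prostate stays open too.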

How the results depend on the processing

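The 20% gene filter with its combinations was chosen after the data were seen; the other alternatives were not. edgeR's 0 higher and 0 lower genes stayed at 0 under RLE and upper-quartile factors, no gene filter, no block, each sum left out, thinned cells, limma, the highest cell left out, and the 3 cell filters. For basal-like cells they stayed at 0 with clusters at resolution 1.2, where a cluster of 13 cells with a median of 178340 counts and 28.051% mitochondrial counts had no name and was left out. At resolution 0.4 every cluster was named basal epithelial-like, so the cells were those of the main test and the counts could not differ. DESeq2 gave 927 and 534 for all and for basal-like cells and 393 between batches. With the 20% filter edgeR gave 0 and 0, with thinned cells 50 and 15, without each gene's highest cell 8 and 0, with DESeq2 454 and 296, and with a sum left out 0 to 71 higher and 0 to 23 lower (68 and 23 without naive batch 2, 71 and 13 without naive batch 3), where the lone sum is assumed to vary like the other group. Dropping the replicate block gave 0 and 0 in both gene sets and changed no call of a named gene or called list in the main gene set. The 13 called lists were 12 to 17 over the alternatives without that filter (17 without a gene filter, 16 with DESeq2 and 16 without the highest cells) and 9 to 13 with it. The 9 with the filter alone include JAK-STAT3 signalling, not called before. They leave out G2 and M phase, S phase, acute phase, type I interferon and a list not reported here. With an estimated correlation 0 were called in either gene set, but with 1 residual degree of freedom that form could hardly call any list. The cause of these changes was not tested.

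Of 2169 values of 90 named genes over 25 alternatives, 1923 kept direction and side of the threshold, 225 newly passed it and 21 reversed. Reversed log2 values were 0.01 for Krt14 without restarted numbering, and for Krt8 0.02 with upper-quartile factors, 0.0 without the gene filter, 0.05 thinned, 0.02 with limma, 0.01 without restarted numbering and 0.06 thinned with the 20% filter. With a sum left out, the ranges were -0.30 to 0.10 for Dcn, -0.29 to 0.23 for Krt14, -0.46 to 0.15 for Krt18, -0.32 to 0.32 for Krt8 and -13.31 to 2.67 for Svs2. Of 324 values of the 12 called lists reported, 263 kept their call, 61 lost it and 0 reversed. The losses include all 12 lists with an estimated correlation in either gene set, a form that could hardly call any list. They also include G2 and M phase under the 20% gene filter, which left 3 of its genes. The cause of the losses was not tested. The share of genes with the same direction was 58.2% thinned and 61.9% without the highest cells. Of 16 shares of cells, 9 moved beyond their interval with at least 5 reads. Depth and the number of cells limit the genes with 0 to 3 counts in a naive sum. Folds against a sum of 0 are bounds for counting error only, since another naive cell with reads could lower them greatly. In naive batch 3, for example, 1 cell gave 98.1% of the 324 reads of Il1r1.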

Other observations

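The sterol list and its test were chosen only after the result was seen.

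Of the genes of sterol synthesis, more than Hmgcs1 and Insig1, the pair that drew attention to them, had fewer reads in inflamed cells. Without these 2, the list held 20 genes, of which 13 were lower and 0 higher in both batches and 6 lower at an unadjusted p under 0.05, but 0 adjusted over the list alone. Its medians were -1.945 in batch 2 and -1.817 in batch 3, below all 10000 random lists in both, which describes these libraries, and camera was not run on this list. Reduced sterol synthesis in inflamed cells may be a pattern to follow up, as a hypothesis found and tested on the same data, with the conditions prepared apart.

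In 24 genes with 0 reads in naive batch 2 and at least 100 CPM in an inflamed sum, 21 had reads in naive batch 3, at a median of 0.0998 CPM and up to 50.2 CPM. In inflamed batch 2, the number in the titles started again, so that 13 of its cells carried numbers from 1 to 13.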
